A study of Caenorhabditis elegans with 2 samples.

How the data were processed

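Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole late embryos of the C. elegans strain OP708, in which a transgene supplies C38D4.7 with a C-terminal EGFP tag and a working copy of unc-119, and the precipitation used an antibody against GFP. The reference annotation describes the C38D4.7 product as a C2H2-type domain-containing protein. The 2 samples are biological replicates 1 and 2 of 1 group, per the labels, aged 4 hours and synchronised by bleaching, with chromatin sheared by sonication to a stated range of 200 to 800. No second condition and no control list was used here, so no comparison between groups was made, and every p-value below describes peaks, genes or sequence windows, not samples.

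The 4 deposited lists give regions on assembly ce11. According to the deposited read-me texts, the authors called candidate regions for each replicate separately and for both replicates' pooled alignments, each against the same control alignment, and then derived optimal peaks with the irreproducible discovery rate (IDR), a measure built on the ranks of regions in both replicates. The caller, the aligner and the IDR threshold are not given in the sources used here. Each deposited line carries the authors' score, a positive number whose scaling is not stated, which was used only to rank or describe peaks within its own list. It also carries −log10 of the authors' q-value, which reached at most 3.06 in the optimal list, where 581 of 649 lines shared that top value, so it could not order the peaks. The position of the summit, the point of highest signal, comes from the deposited offset within each region. The read depth behind the regions is unknown, since the lists hold no read counts. Binomial intervals below cover counting error over peaks only.

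The optimal list held 649 lines at 627 distinct regions, because some regions were listed once for each of several summits, and every line was kept as a peak. These were exactly the 649 highest-scoring lines of the pooled list. The pooled and replicate 1 lists both ended at 30000 lines and the replicate 2 list held 26661, so presence near the end of a list depends on its length. The 29351 pooled candidates outside the optimal set served as the lower-ranked background.

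Gene positions and sequence came from the RefSeq annotation and sequence of WBcel235, the same assembly as ce11. A promoter was the stretch from 1000 bp upstream to 200 bp downstream of the start of a protein-coding gene, and a promoter was called bound when it held an optimal summit. A noncoding gene counted as near a peak when the summit lay within 200 bp of it. Shares at promoters and overlaps between replicates (at least 1 bp) were set against 1000 random circular shifts of the summits or regions within each chromosome, with a two-sided permutation p whose smallest possible value was 0.002. The share of peaks on X was tested with an exact binomial test against the X share of the assembly length. Fisher's exact test, two-sided, was used for 7 noncoding classes, for 19 gene lists and for 2080 6-mers (both strands together), with Benjamini-Hochberg adjustment and a threshold of 0.05. List symbols that RefSeq has renamed were matched through the Ensembl symbol of the same gene. This matching was added after a first run of the list tests had been seen. With RefSeq symbols alone the ribosomal protein list held 65 genes, of which 7 were bound (10.8%, adjusted Fisher's exact p = 0.00157), and 5 of 19 lists passed, as with the matching. The 6-mers were counted in windows of 50 bp either side of the summit, against windows centred 300 bp to each side, first on chromosomes I, II and III, and those past the threshold were tested again on IV, V and X. Spearman's rho was computed across peaks, which are not independent replicates, with a bootstrap interval from 1000 draws.

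The rule for named items was fixed before the data were examined. It took the protein-coding gene with the nearest start within 2000 bp, and any noncoding gene within 200 bp, for the 15 highest-scoring peaks. It also took up to 4 members with the highest-scoring promoter peak from each gene list past the threshold and up to 2 from each other list, then C38D4.7 and unc-119, and finally the 5 6-mers with the smallest p in both sets of chromosomes. The tests, gene lists and most alternatives were also set before the data were examined. Alternatives without the mitochondrial regions, and those splitting peaks by nearness to tRNA, snRNA, snoRNA and rRNA genes, were chosen after seeing the data, as were the descriptions of gene families and summit positions. The alternatives set beforehand were other overlap rules, other window sizes, the 324 highest-scoring optimal peaks, other backgrounds, and leaving out each replicate, for which the top 649 candidates of the other replicate stood in for the optimal peaks.

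The tests were checked on simulated data. Over 20 simulations of 19983 protein-coding genes, in which 3 lists were given 0.2 of their promoters bound against 0.02 elsewhere, 95.0% of the raised lists were recovered and 1.25% of the other lists were called. The lists called in the data had lower shares, from 9.76% to 18.9%, so this recovery rate does not apply to them. Each promoter was also drawn independently, although 1 summit can lie in the promoters of several genes. Over 20 simulations of 4 noncoding classes, all 40 raised classes were recovered and 0 of 40 others were called. Apart from the planted summits, both sets of summits there were placed at random on the nuclear chromosomes, unlike real candidates. Over 5 simulations of 2080 6-mers, 14 of 15 planted 6-mers were recovered and 2 of 10385 others were called. Both sets of windows in the 6-mer simulations were drawn at random from the genome. Their rate of false calls therefore does not cover differences in base composition between summits and flanks. Analyses used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.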

Results

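Binding of GFP-tagged C38D4.7 was mapped by ChIP-seq in late C. elegans embryos, with 2 biological replicates of the tagged strain. The authors' optimal list held 649 peaks, drawn from 30000 candidate regions in replicate 1, 26661 in replicate 2 and 30000 in the pooled alignments. The optimal peaks had a median region width of 470 bp, and the authors' score, used here only within its own list, ran from 180.1 to 6973.

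The first question was where in the genome the tagged protein was found. The nuclear peaks fell mainly at genes for small structural RNAs and at promoters of protein-coding genes. When each optimal summit was given 1 class, 213 of 649 lay within 200 bp of a nuclear tRNA gene (32.8%, 95% exact binomial interval 29.2 to 36.6), 58 near a snoRNA gene (8.94%, 6.86 to 11.4) and 12 near an snRNA gene (1.85%, 0.959 to 3.21). A further 219 lay at a protein-coding promoter away from those genes (33.7%, 30.1 to 37.5), 20 lay on the mitochondrial genome and 127 lay elsewhere. The make-up changed with rank. Among the 100 highest-scoring peaks, 34 were at tRNA genes, 28 at snoRNA genes and 16 at promoters. The counts were 101, 17 and 73 of 224 peaks at ranks 101 to 324, where the tRNA share was highest (45.1%), and 78, 13 and 130 of 325 peaks at ranks 325 to 649. No list from an untagged strain or another tagged protein was used here. Whether the peaks are specific to C38D4.7 was therefore not tested. This holds for those at small RNA genes, on the mitochondrial genome and at promoters, and so for the gene lists below.

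**Figure D1:**
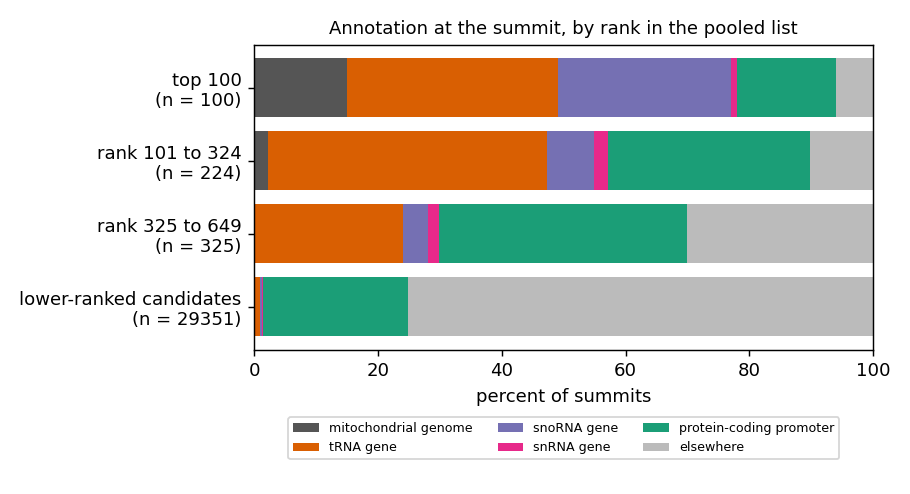
Share of summits (x axis, percent) in each annotation class for 3 rank ranges of the optimal list and for the 29351 lower-ranked pooled candidates, 1 bar per range. Summits at snoRNA genes made up 28.0% of the top 100 and 0.365% of the lower-ranked candidates, and summits at tRNA genes 34.0% and 0.852%.

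The highest-scoring peaks were on the mitochondrial genome and at snoRNA genes. Of the top 15 peaks, 10 were mitochondrial, and the best of these had its summit at position 5602 in CYTB, a subunit gene of respiratory complex III, with a score of 6973. The nearest protein-coding starts to these 10 summits belonged to COX1, COX2, COX3, CYTB, ATP6, ND4 and ND5, all of which encode subunits of the respiratory chain or ATP synthase, and the mitochondrial tRNA genes for leucine, cysteine, methionine, aspartate and glycine lay within 200 bp of some of them. The highest nuclear summit, at position 11960837 on chromosome II with a score of 2050, lay just upstream of the snoRNA gene W03C9.9 (II, 11960898 to 11960959, plus strand) and 1291 bp inside the start of W03C9.1. It ranked 9 in replicate 1 and 14 in replicate 2. The next was on chromosome V at position 12303641, beside the snoRNA genes C51F7.3 and C51F7.4, with F55C5.17 as the nearest protein-coding start. Peaks at the snoRNA genes T06C12.16 (V, position 15873975, nearest start str-56) and T03F7.8 (V, position 11314215, beside the unclassified noncoding gene T03F7.14) ranked 13 and 15. The highest peak at a nuclear protein-coding promoter ranked 12 and lay 531 bp upstream of K12H4.5 on chromosome III, at position 8043956.

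The 2 replicates named largely the same regions. Of the 649 highest-ranked candidates of replicate 1, 468 overlapped one of the 649 highest-ranked of replicate 2 by at least 1 bp (72.1%), whereas random shifts gave 4.17% on average and 5.39% at most (permutation p = 0.002, the smallest the shifts can give). Most of this chance level came from mitochondrial regions. Without them 444 of 625 overlapped (71.0%), and random shifts gave 0.544% on average and 1.76% at most. Spearman's rho between the ranks of the best overlapping candidate in the replicate lists was 0.822 across 647 optimal peaks (bootstrap interval 0.785 to 0.854), a correlation across peaks that are not independent replicates. The authors chose the optimal peaks from both replicates together, so this correlation is no independent measure of how far the replicates match. In the replicate lists 572 of the optimal peaks ranked within the top 649 of replicate 1, 517 within that of replicate 2 and 462 within both.

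**Figure D2:**
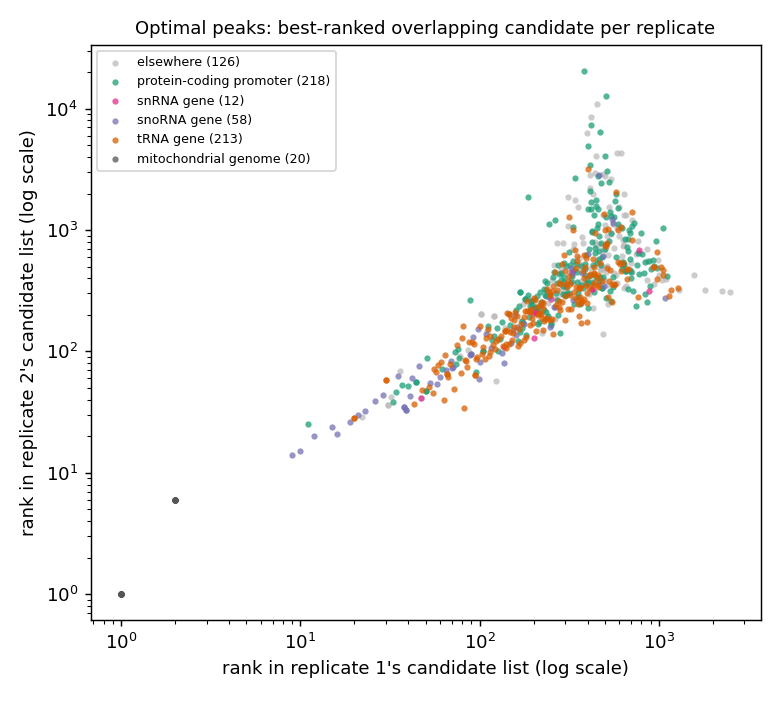
Rank of the best overlapping candidate in replicate 1 (x axis, log scale) against that in replicate 2 (y axis, log scale) for the 647 optimal peaks with a candidate in both, 1 point per peak, coloured by annotation class. The ranks follow each other at the top and spread apart further down, with rho of 0.822 over the whole set.

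Genes for small structural RNAs were found at optimal peaks far more often than at lower-ranked candidates. With mitochondrial genes included, 33.7% of optimal summits were near a tRNA gene against 0.852% of lower-ranked summits (odds ratio 59.3, adjusted Fisher's exact p = 1.454e-244), 8.94% against 0.365% were near a snoRNA gene (odds ratio 26.8, adjusted p = 1.126e-53) and 2.00% against 0.123% near an snRNA gene (odds ratio 16.6, adjusted p = 4.539e-11). Unclassified ncRNA genes were near 35.0% against 7.69% (adjusted Fisher's exact p = 1.452e-83). The classes overlap, and at some summits, such as those of rank 15, 27, 33, 39 and 45, such genes lay beside tRNA or snoRNA genes. Part of this share therefore counts the same summits again. Precursors of miRNA were near 6 optimal summits, 0.924% against 0.204% (adjusted Fisher's exact p = 0.00354), a call lost with the 324 highest-scoring peaks (adjusted p = 0.172) and without replicate 2 (adjusted p = 0.0638). The rRNA class passed with 3 summits, adjusted Fisher's exact p = 1.411e-05, but all 3 were mitochondrial and 0 of 629 nuclear peaks lay near an rRNA gene. Long intergenic noncoding genes did not pass, with 2 summits (0.308% against 0.371%, adjusted Fisher's exact p = 1). Without replicate 1 their direction turned, with 6 summits (0.924% against 0.419%, odds ratio 2.22, adjusted Fisher's exact p = 0.0623).

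Seen from the genes, each family was described by how many members held an optimal peak within 200 bp, with no test between families. Of the 612 nuclear tRNA genes, 221 did (36.1%, 95% exact interval 32.3 to 40.1), and 395 had some candidate in the pooled list. By contrast 3 of 209 tRNA pseudogenes had an optimal peak. Of 344 snoRNA genes, which guide the modification of other RNAs, 56 had one (16.3%, 12.5 to 20.6). Among the genes for SL2, a leader RNA that is spliced onto downstream genes of operons, 4 of 18 had one, namely sls-2.1, sls-2.2, sls-2.4 and sls-2.9, while 0 of 12 genes for the related SL1 RNA had even a pooled candidate. Of 22 short snRNA genes that carry ACAGAGA, a sequence typical of the U6 spliceosomal RNA, 4 had one, the highest-ranked being W05B2.8 at rank 42, while 4 of the 67 other snRNA genes (5.97%) and 0 of 12 smy RNA genes had one. The genes for RNase P RNA (rpr-1) and RNase MRP RNA (mrpr-1), which process tRNA and rRNA precursors, lay within 200 bp of the peaks of rank 26 and 82. None of the 16 annotated copies of the 5S rRNA gene had a pooled candidate. The 95% exact intervals of the small families overlapped, with 6.41 to 47.6% for SL2 and 0 to 26.5% for SL1. The same held for the U6-like genes (5.19 to 40.3%) and the other snRNA genes (1.65 to 14.6%). These families were named after their values were seen. The SL1, 5S and U6-like genes include identical copies, for which the placing of shared reads is not given in the sources used here.

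Summits sat at different places at the different kinds of gene. At tRNA genes the median summit lay 16 bp inside the gene from its 5′ end (quartiles 5 and 50 bp), and at snoRNA genes 49 of 58 summits lay upstream, with a median of -44 bp (quartiles -57 and -17.5 bp). The medians differed by 60 bp (permutation test with 100000 resamples, two-sided p = 2.000e-05, the smallest it can give). At protein-coding promoters, where the window itself limits the range, the median was -207 bp.

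**Figure D3:**
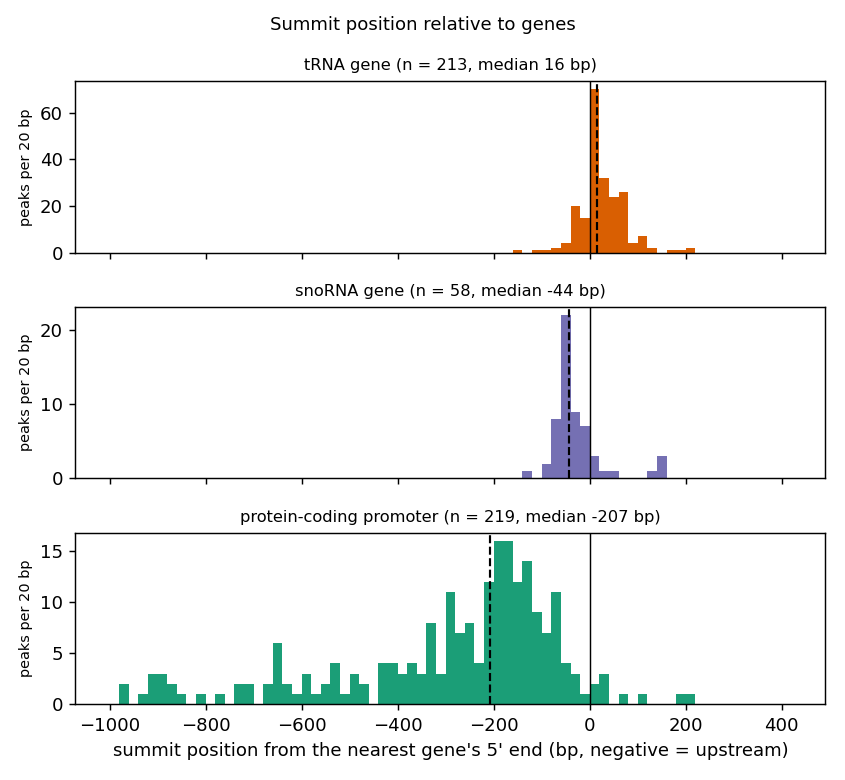
Number of optimal peaks per 20 bp (y axis) by distance of the summit from the 5′ end of the nearest gene of the class (x axis, bp, negative is upstream), for tRNA genes, snoRNA genes and protein-coding promoters. The dashed lines mark medians of 16, -44 and -207 bp.

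Promoters of protein-coding genes held optimal peaks more often than chance placement gives. In all, 299 of 649 summits (46.1%, 95% exact interval 42.2 to 49.99) fell in a promoter, against 22.6% on average over random shifts (highest 27.6%, permutation p = 0.002) and 23.8% of lower-ranked candidates (odds ratio 2.74, Fisher's exact p = 1.950e-34). The excess lay in the peaks away from small RNA genes, of which 219 of 346 were at promoters (63.3%, permutation p = 0.002). Of the 283 nuclear peaks near tRNA, snRNA, snoRNA or rRNA genes, 64 were at promoters (22.6%), against 20.5% over random shifts (permutation p = 0.4276). Altogether 385 of 19983 protein-coding genes, those of the mitochondrial genome included, had a bound promoter.

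Of the 19 gene lists, 5 had promoters bound more often than those of other genes, and no list of tissue genes was among them. Of the translation factors 7 of 37 were bound (18.9% against 1.90% of other genes, odds ratio 12.1, adjusted Fisher's exact p = 1.109e-04). The 4 with the highest-scoring peaks were eif-3.C (rank 114), eif-3.I (rank 382), eif-3.E (rank 448), all subunits of initiation factor 3, and iff-2 (rank 525), an eIF5A homologue. Of the mitochondrial respiratory chain genes encoded in the nucleus, 7 of 45 were bound (15.6%, odds ratio 9.53, adjusted Fisher's exact p = 1.789e-04), including cox-6A (rank 170), nduf-9 (rank 426), nduf-11 (rank 478) and mev-1 (rank 562), a succinate dehydrogenase subunit, although the cox-6A peak also lay beside the snRNA gene F54D8.7. Of the cytosolic ribosomal protein genes 9 of 82 were bound (10.98%, odds ratio 6.40, adjusted Fisher's exact p = 1.789e-04), led by rpl-3 (rank 176), rps-26 (rank 246), rps-28 (rank 257) and rpl-15 (rank 270), of which the rps-26 peak also lay near a small RNA gene.

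The other lists past the threshold were regulators and stress genes. Chromatin and transcription regulators had 6 of 59 promoters bound (10.2%, odds ratio 5.84, adjusted Fisher's exact p = 0.00445), led by lin-35 (rank 203), the worm retinoblastoma homologue, cbp-1 (rank 221), a histone acetyltransferase, cdk-9 (rank 304), a kinase of transcription elongation, and mrg-1 (rank 330). Heat shock and unfolded protein response genes had 4 of 41 (9.76%, odds ratio 5.55, adjusted Fisher's exact p = 0.0298), which were hsp-60 (rank 217), dnj-19 (rank 344), hsp-1 (rank 366) and atf-6 (rank 626). The 5 calls depended on the setting. With only genes holding a pooled candidate as background, translation factors (adjusted Fisher's exact p = 0.0152) and respiratory chain genes (adjusted p = 0.0256) passed, while the odds ratios of the 3 others were 2.62 to 3.68. Among the 324 highest-scoring peaks only ribosomal protein genes passed (adjusted Fisher's exact p = 0.0211). With these fewer peaks the odds ratio of the chromatin and transcription regulators was 5.65, whereas those of translation factors, respiratory chain and heat shock genes were 2.90, 2.37 and 2.61. Without replicate 2 the respiratory chain genes no longer passed (3 of 45, 6.67%, odds ratio 3.74, adjusted Fisher's exact p = 0.201). Without replicate 1 the heat shock genes did not (3 of 41, odds ratio 4.45, adjusted Fisher's exact p = 0.133). The order of the lists also changed, since translation factors stood at 10.8% without replicate 1 and 13.5% without replicate 2, below the respiratory chain genes (11.1%) in the former and the heat shock genes (14.6%) in the latter. With promoters from 500 bp upstream to 100 bp downstream the heat shock genes did not pass either (3 of 41, adjusted Fisher's exact p = 0.0684), although their odds ratio was 5.796.

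None of the 14 other lists passed the threshold, with adjusted Fisher's exact p from 0.581 to 1 and an unadjusted p of at least 0.184. Of the homeobox genes 0 of 100 were bound, of neuronal genes 0 of 50, of intestinal genes 0 of 49, of hypodermal and seam genes 0 of 63 and of pharyngeal genes 0 of 32. The upper 95% exact bounds on these shares were 3.62%, 7.11%, 7.25%, 5.69% and 10.9%, all above the 1.93 to 1.94% of other genes, so lists of this size could not show a lower share. Body wall muscle genes had 1 of 47 bound (unc-112), cilia genes 1 of 42 (daf-19), germline genes 1 of 53 (mex-1), proteasome genes 1 of 31 (rpn-7), core histone genes 1 of 82 (his-72) and DNA replication and mitosis genes 1 of 38 (knl-1). Nuclear hormone receptor genes had 2 of 274 (nhr-255 and nhr-47), collagen genes 2 of 156 (col-185 and col-85) and spliceosome genes 2 of 53 (snr-1 and snr-4), and the peaks at nhr-255, col-185, col-85 and snr-4 were also near a small RNA gene.

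**Figure D4:**
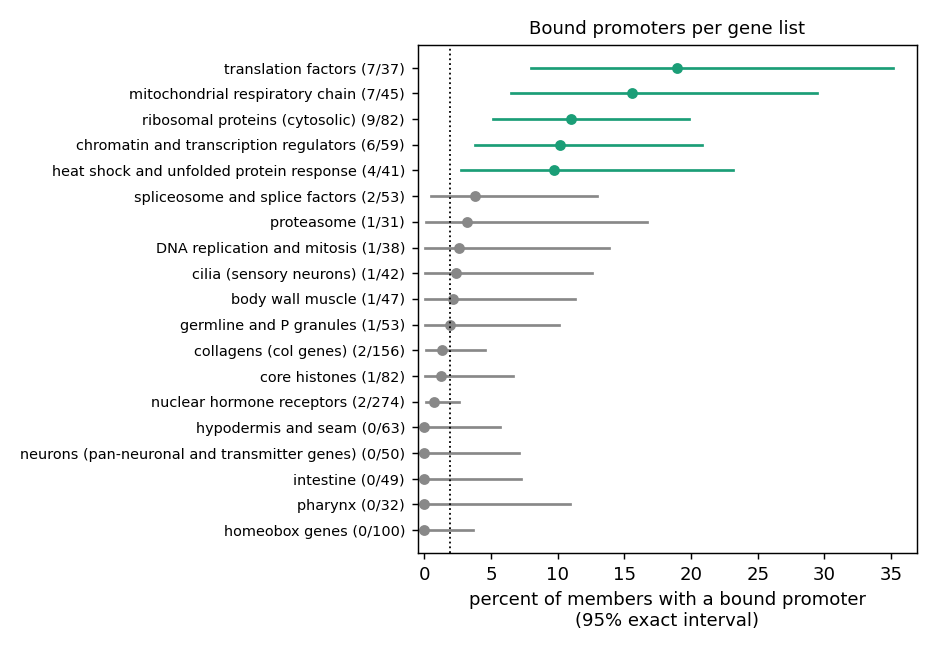
Percent of members with a bound promoter (x axis) for each of the 19 gene lists, with 95% exact binomial intervals as lines. Lists past the adjusted threshold are green and the others grey, and the dotted line is the mean share among genes outside each list. Translation factors stand at 18.9% and homeobox genes at 0.

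The X chromosome held 153 of 649 optimal peaks (23.6%, 95% exact interval 20.4 to 27.03), more than its 17.7% of the assembly length (exact binomial p = 1.356e-04) and its 15.4% of lower-ranked candidates (odds ratio 1.70, Fisher's exact p = 6.911e-08). X also carries 276 of the 612 nuclear tRNA genes (45.1%). Among the 213 nuclear peaks near tRNA genes 92 were on X (43.2%), whereas among the 416 nuclear peaks away from them 61 were (14.7%, 11.4 to 18.4), no more than the X share of the assembly (exact binomial p = 0.123). Single tRNA genes on X were not bound more often, with 97 of 276 holding an optimal peak (35.1%) against 124 of 336 on the autosomes (36.9%, Fisher's exact p = 0.673).

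**Figure D5:**
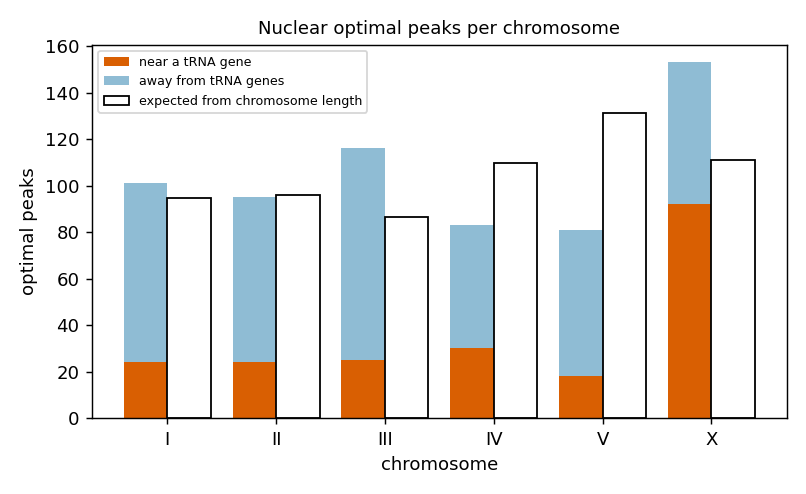
Optimal peaks on each nuclear chromosome (y axis, count), split into those near and away from tRNA genes, beside the number expected from chromosome length (open bars). Chromosome X held 92 peaks near tRNA genes and 61 away from them.

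Sequences at the summits divided along the same lines. Of 2080 6-mers, 195 were more frequent at optimal summits than 300 bp away on both chromosome sets, and 124 were less frequent. The 5 with the smallest p were CGAACC, CGCACA, GTTCGA, CCGCCC and CCGCAC. On chromosomes I, II and III CGAACC was in 12.8% of summit windows against 1.76% of flanks (adjusted Fisher's exact p = 3.186e-09), and on IV, V and X in 20.2% against 2.05% (adjusted p = 3.077e-18). For CCGCAC the shares were 11.5% against 2.08% (adjusted Fisher's exact p = 3.177e-07) and 10.4% against 1.42% (adjusted p = 1.321e-08). Over all nuclear peaks GTTCGA was in 19.1% of summit windows, CGCACA in 12.4% and CCGCCC in 11.9%. The tests counted each window as independent. Of the 612 nuclear tRNA genes, however, 469 have at least 1 identical copy, and windows at such copies share sequence. For 6-mers that lie in tRNA genes the p-values may therefore be too small. For these 6-mers the second chromosome set is also no independent check. In the peaks away from small RNA genes, 68 6-mers were more frequent on both chromosome sets and 28 less frequent. There CGAACC (2.31% of windows) and GTTCGA (3.18%) no longer passed, whereas CCGCAC was in 18.7% of windows against 2.07% of flanks on I, II and III (adjusted Fisher's exact p = 4.514e-09) and 17.6% against 1.31% on IV, V and X (adjusted p = 1.680e-08).

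The strain carries added copies of C38D4.7 and unc-119, so the source loci on chromosome III were looked at apart. No optimal peak lay within 20 kb of C38D4.7 (III, 4810031 to 4811295, minus strand) or of unc-119 (III, 10902641 to 10908935, plus strand), where the mean density on the chromosome predicts 0.347 and 0.390. The pooled list had 12 candidates around C38D4.7 (16.2 expected) and 25 around unc-119 (18.2 expected), the best at ranks 1201 and 909. Within 20 kb of C38D4.7 the best candidate ranked 1527 in replicate 1 but 404 in replicate 2. Around unc-119 these ranks were 1321 and 812. Within 50 kb, 1 optimal peak appeared, at rank 284 on the unc-119 side near tmie-1, a gene named after its value was seen. At that distance the mean density predicts 0.852 peaks around C38D4.7 and 0.895 around unc-119.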

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

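Alternatives that split peaks by nearness to small RNA genes or left out mitochondrial regions were chosen after seeing the data, and the others were planned. Of 142 alternatives, 118 kept their direction and their side of the threshold, or stayed within the limits set for values without a test. The overlap of replicates did so in all 5 (55.5 to 86.1%), the number of noncoding classes past the threshold in all 5 (5 or 6, against 6), and the share at promoters in 8 of 9. The exception was the nuclear peaks near small RNA genes, at 22.6%. The share on X turned to 14.7% with peaks away from tRNA genes, which is below the X share of the assembly, and stayed above it in the other 5. The rank correlation between replicates rose to 0.895 in the 324 highest-scoring peaks; the cause was not tested. Gene lists past the threshold fell from 5 to 1 with those 324 peaks, which bind fewer promoters, and to 2 with only genes holding a pooled candidate as background. The 6-mers more frequent at summits fell from 195 to 94 in windows of 25 bp either side, which are shorter. They fell to 68 in peaks away from small RNA genes, which are fewer and in which CGAACC was in 2.31% of windows and GTTCGA in 3.18%. Within 50 kb of the transgene's source loci 1 optimal peak lay, where 0.852 and 0.895 are expected at the 2 loci, against 0 within 20 kb. Leaving out each replicate gave 42.8 to 44.99% at promoters, 20.8 to 24.0% on X, 4 gene lists either way and 5 to 6 noncoding classes. It also gave 152 to 165 6-mers more frequent at summits. Overlap and rank correlation need both replicates and have no such value. No paired analysis was possible because there is 1 group. Read depth could not be judged from these lists.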

Other observations

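The tests in this part were chosen after the main results were seen. For the comparisons of tRNA genes with ribosomal protein promoters and for the coverage of the mitochondrial genome, the reading of the test was also written after its value was known. Promoter peaks often lay in the promoter windows of genes on both strands. Of the 219 peaks at promoters away from small RNA genes, 80 did so (36.5%), against 927 of 6884 lower-ranked candidates at promoters (13.5%, odds ratio 3.70, Fisher's exact p = 3.946e-17). The highest-scoring of these promoter peaks, after K12H4.5, were nearest to the starts of atx-2 (rank 29, 82 bp upstream), ears-2 (rank 32, 42 bp upstream), a glutamyl-tRNA synthetase, and idhg-1 (rank 36, 281 bp upstream), an isocitrate dehydrogenase subunit. Beyond the small RNA classes and promoters, single high peaks lay beside the miRNA genes mir-51 (rank 22) and mir-52 (rank 31).

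Peaks at tRNA genes were spread over the amino acids. Among 22 groups of nuclear tRNA genes, 21 by product and 1 of the 5 genes without a named product, none passed after adjustment, and tRNA-Cys, with 10 of 13 genes at an optimal peak, came closest (adjusted Fisher's exact p = 0.0660). It and tRNA-Ala (19 of 34, adjusted Fisher's exact p = 0.184) were the ones with an unadjusted p under 0.05. Among snoRNA genes, 31 of 212 inside a protein-coding gene had an optimal peak (14.6%) and 25 of 132 outside one (18.9%, Fisher's exact p = 0.297).

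The peaks at nuclear tRNA genes invite a technical reading, since 469 of the 612 genes have at least 1 identical copy. If reads shared between identical copies were the whole cause, tRNA genes of unique sequence would rarely hold a peak, yet 33 of 143 did (23.1%, 95% exact interval 16.4 to 30.9). Genes with a copy held one more often (40.1%, odds ratio 2.23, Fisher's exact p = 2.169e-04), so shared reads may add to the signal at some genes. Unique sequence here means only that no identical full-length copy exists. Reads shared with near-identical copies, and peaks of a neighbouring gene within 200 bp, were not set apart. The test therefore cannot exclude shared reads. Enrichment at every strongly transcribed gene would predict that ribosomal protein promoters are bound about as often. Of them 10.98% were (5.14 to 19.8), below the lower bound of 32.3% for all tRNA genes, a share that shared reads may raise. For tRNA genes of unique sequence the intervals overlapped (odds ratio 2.43, Fisher's exact p = 0.0322). The windows used for promoters and for tRNA genes also differ in size. Ribosomal protein promoters were themselves bound more often than those of other genes (10.98% against 1.89%). Enrichment at strongly transcribed genes therefore stays open. Enrichment that any immunoprecipitation gives at genes transcribed by RNA polymerase III was not tested, because no precipitation of another protein was used here, and the design gave no second group for a biological test.

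The mitochondrial summits among the highest scores are a second pattern. Nuclear optimal regions had a median width of 470 bp and a largest width of 606 bp. The whole pooled list also had a median of 470 bp, so this width is not particular to the optimal peaks. The 20 mitochondrial summits instead fell in 2 regions that cover 94.0% of the 13794 bp mitochondrial genome. That spread is consistent with many mitochondrial genome copies in the libraries as their source, although the control alignment was meant to account for it. Whether the tagged protein enters mitochondria, or whether precipitation of another protein gives the same regions, was not tested, and leaving these peaks out moved the share at promoters to 44.99% and rho to 0.805.

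The 6-mer CCGCAC at promoter peaks was also weighed. Promoter summit windows were GC-rich, with a median GC content of 48.5% against 39.6% for lower-ranked promoter candidates, so base composition was tested. CCGCAC was in 54 of 219 windows (24.7%), against 43 of 1082 windows of the same GC count (3.97%, odds ratio 7.91, 95% interval 5.01 to 12.5, Fisher's exact p = 6.187e-20), which argues against GC content as the whole cause. The 6-mer was picked for its frequency at these same summits, so this odds ratio may be too high. Matching covered the GC count only, not the order of the bases. Binding at the 6-mer itself would centre it on the summit, but 37 of 61 occurrences lay within 25 bp (60.7%, 47.3 to 72.9), an interval that includes the 52.1% of an even spread, so binding by C38D4.7, by a partner, or a feature shared by these promoters cannot be told apart. The base just before the 6-mer was G in 73.8% of the 61 occurrences, and the base after it was A in 50.8% and G in 41.0%.

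A hypothesis was that the snoRNA peaks carry the B box, the internal promoter element of tRNA genes that binds the RNA polymerase III factor TFIIIC. The pattern GTTCGA, any 2 bases, then C was in 13 of 58 snoRNA summit windows (22.4%, 12.5 to 35.3) and in 0 of the flanks (Fisher's exact, adjusted p = 5.803e-07 over 5 classes). At tRNA summits it was in 38.03% of windows against 2.35% of flanks (adjusted Fisher's exact p = 2.244e-32), and at promoter summits in 3 of 219 (adjusted p = 0.425). The element is part of tRNA genes themselves, and the tRNA class was defined by summits within 200 bp of such genes, with flanks 300 bp away. The tRNA contrast therefore follows from the choice of windows and says nothing about binding. The snoRNA result is what tRNA-type promoters at part of the snoRNA genes with a peak would give. GTTCGA, which begins the pattern, had however already been picked for its frequency at all nuclear summits, those at snoRNA genes included. The same flanks were used, so the snoRNA contrast is no independent test and may be too high. The position of the element relative to the gene was not tested.

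Further gene groups were tried on the hypothesis that promoter peaks extend to genes of mitochondrial translation and tRNA charging. Of 69 mitochondrial ribosomal protein genes 4 had a bound promoter (5.797% against 1.91%, adjusted Fisher's exact p = 0.0882 over 2 lists), namely mrpl-15, mrpl-23, mrpl-39 and mrps-28, and the peaks at mrpl-23 and mrps-28 also lay near a small RNA gene. Of 32 aminoacyl-tRNA synthetase genes 1 had one, ears-2 (3.12%, adjusted Fisher's exact p = 0.464). Neither passed. The reading written down beforehand counted a missed threshold against the hypothesis. That reading was changed after the values were seen, because with so few bound members a higher share is not excluded, and the question is left open.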
